A study of Homo sapiens with 68 samples.

How the data were processed

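Pooled CRISPR knockout screens were analysed, in which each cell carries a single guide RNA against 1 gene and the abundance of each guide is read by sequencing. The labels describe 68 samples of 2 human cell lines in 4 screens. The line ES-2-MC2-Liver is given per the labels as an ovary cancer cell and carried a phosphatase library, a metabolism library and a mini library. SKHEP-1, given as a hepatocarcinoma cell, carried the mini library. Per the series design, cells were collected before implantation, were put into the peritoneum, and cancer cells were taken from livers, lungs and subcutaneous tumours. Values were present for 58 libraries. The other 10 samples, all of the ES-2 mini screen, were pre-injected cells (4), cells cultured for 7 doublings (4) and cells cultured for 7 days (2), and their 3 comparisons are not analysed here.

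The deposited values are guide abundances with the unit signal, scaled by the authors with 1 factor per library. The phosphatase table was scaled to the median and the other 3 tables to control guides, as far as the deposited table names say. In the ES-2 mini table the control guides nevertheless had medians from 748 to 5881, alike only within a replicate number, so its libraries do not share 1 scale. In each library the values were whole multiples of 1 step within a tolerance of 0.05, so sequencing reads per guide were recovered as estimates by dividing by that step. The submitters' processing notes list MAGeCK 0.5.9.4 and the build hg38 with no role; how reads were assigned to guides is not given in the sources used here. Gene positions are from the annotation of GRCh38, the build that hg38 names. Gene symbols are printed as in the current annotation, or as deposited where no single match was found (AGPAT9). Where the 2 differ, the deposited symbol is given at first mention. PLPPR2 and PLPP1 were deposited as LPPR2 and PPAP2A.

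For each library, a gene score was the mean over the gene's guides of log2(value + 1). Guides with a mean of at least 10 in the pre-injected cells and genes with at least 3 such guides were used. The filter kept 44.966% of the gene guides of the metabolic screen (13354 guides, 2618 of 2978 genes). It removed nothing in the phosphatase screen (288 genes) or in the SKHEP-1 mini screen (99 genes). It could not be applied in the ES-2 mini screen (99 genes), for which no pre-injected values were at hand. The scores of the 2 parts of each SKHEP-1 lung were averaged, so that n is the number of replicates and not of libraries. Groups were compared with limma 3.58.1 in R 4.3.3 with 1 mean per group and a spread shared by all libraries of a screen except the plasmid, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. The single pre-injected library of the phosphatase and metabolic screens was assumed to vary like the other groups. These p-values measure the spread between the samples at hand. Errors of log2 fold changes are standard errors from limma.

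Recovered reads per library, in megareads (M), ran from 4.13 M to 31.3 M in the phosphatase screen and from 11.9 M to 28.7 M in the metabolic screen without its plasmid. They ran from 0.394 M to 7.81 M in the ES-2 mini screen and from 0.0466 M to 19.1 M in the SKHEP-1 mini screen. In the metabolic screen the median guide had 10 recovered reads in the pre-injected cells and 8 to 16 in the animal samples, so single guides were measured with low precision there. Reads without molecular identifiers are not independent molecules.

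Gene lists, 30 in all, were fixed in advance and tested with camera of limma where at least 5 members were measured, with a preset inter-gene correlation of 0.01 and again with an estimated correlation. Their p-values were adjusted over the lists and over the comparisons against subcutaneous tumours within a screen. Unevenness of guides was measured per library by the Gini index, which is 0 when all guides are equal, and compared by exact two-sided permutation tests adjusted over 12 comparisons. Correlations of fold changes between comparisons with shared subcutaneous tumours were set beside values simulated for unchanged groups.

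The genes named were set by a rule. For each comparison these were the 10 largest decreases and the 10 largest increases past the threshold, and members of the lists past it (at most 6 per list, largest change first). Where fewer than 3 genes passed in a direction, the 5 with the lowest p in that direction are given as not past the threshold. ACSL4, LPCAT3, AGPS, GNPAT, FAR1, ECH1, ECI1 and GPX4 are given wherever measured, and genes named in a primary screen were followed in the mini screens. Beyond about 10 genes in a comparison, the set is summarised with examples. Some results that the rule names are not reported here. The groups, tests, lists, this rule and the alternatives were chosen before the data were examined, except where stated.

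The alternatives were a pseudocount of 10, no guide filter, scaling to the same total, the median over guides, robust rank aggregation of guide ranks with 20000 to 100000 permutations and an alpha of 0.25, the quasi-likelihood test of edgeR 4.0.16 on summed recovered reads, the replicate number as a block, averaging the lung parts before the log2 step, and leaving out each library in turn. Chosen after seeing the data were centring each library on its control guides, a guide minimum of 100 in the metabolic screen, the block without each replicate number in the ES-2 mini screen, and exact sign changes within its pairs for the Gini index. Tables were handled with the R package data.table (version 1.17.8) and Python 3.11.15, and plots were drawn with matplotlib 3.10.9.

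Replicate numbers recur across groups in the labels, which do not say what a number marks. Whether they pair the samples was checked from the correlations of deviations from the group means. In the ES-2 mini screen every same-number correlation was over 0.1, from 0.426 to 0.730 for livers with subcutaneous tumours, from 0.317 to 0.644 for livers with lungs, and from 0.265 to 0.486 for lungs with subcutaneous tumours. Different numbers gave at most 0.259, 0.227 and -0.0194 for the same combinations. These correlations run over genes, so an offset shared by all guides of a library does not enter them. The numbers therefore pair the samples of that screen, and its fit with the replicate number as a block is given beside its results.

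The tests were tested on simulated data laid on the lung against subcutaneous design. The simulated lungs and subcutaneous tumours differed only in the changed genes and in noise of the same spread. Loss of clones in lungs was not simulated, so false calls from it are not measured here. At a log2 fold of 2, limma recovered 10 of 10 changed genes in the phosphatase design, 97 of 100 in the metabolic design and 5 of 5 in the SKHEP-1 mini design. At a log2 fold of 1 it recovered 5 of 10, 41 of 100 and 4 of 5, with 0 of 268, 4 of 2418 and 0 of 89 unchanged genes called. In the metabolic design rank aggregation recovered 31 of 100 changed genes at a log2 fold of 1 and 89 at 2. There edgeR recovered 2 and 24. The measured metabolic lungs against subcutaneous tumours ordered the tools otherwise, as given below, so these shares do not carry over to them. In the paired ES-2 mini design limma without the block recovered 0 of 5 at either fold, and with the block 3 of 5 and 5 of 5, with 1 of 89 unchanged genes called.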

Results

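Guide abundances were measured by sequencing in 4 pooled CRISPR knockout screens of human cancer cells implanted into animals, where a guide that becomes rarer marks a knockout that left fewer cells. The phosphatase screen of ES-2-MC2-Liver cells (shortened to ES-2 from here on, which always means this line and not parental ES-2) had 1202 guides, 50 of them control guides, against 288 genes in pre-injected cells (n = 1), subcutaneous tumours (n = 3), livers (n = 5) and lungs (n = 3). The metabolic screen of ES-2 had 30197 guides, 499 of them control guides, in pre-injected cells (n = 1), subcutaneous tumours (n = 2), livers (n = 5), lungs (n = 5) and the plasmid library (n = 1). The mini library had 496 guides, 100 of them control guides, against 99 genes. It was read in ES-2 subcutaneous tumours, livers and lungs (n = 4 each), and in SKHEP-1 pre-injected cells, cells cultured for 7 doublings, subcutaneous tumours and lungs (n = 4 each, each lung in 2 parts). Recovered reads per library in megareads (M) were 31.3 M in pre-injected cells, 4.13 M to 5.04 M in subcutaneous tumours, 5.24 M to 28.6 M in livers and 13.9 M to 25.6 M in lungs of the phosphatase screen. In the metabolic screen they were 18.6 M, 11.9 M to 25.4 M, 12.7 M to 27.6 M and 20.5 M to 28.7 M for the same groups. The ES-2 mini libraries had 0.394 M to 2.92 M (subcutaneous), 0.912 M to 7.81 M (liver) and 1.02 M to 2.93 M (lung). The SKHEP-1 mini libraries had 0.0837 M to 2.41 M (pre-injected), 0.144 M to 2.56 M (culture), 0.0466 M to 19.1 M (subcutaneous) and 0.490 M to 10.6 M (lung).

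Lung metastases held on average the most uneven guide populations in all 4 screens. The Gini index of guide values averaged 0.671 ± 0.0603 (SD, n = 3) in phosphatase lungs, against 0.499 ± 0.0482 in livers (n = 5), 0.491 ± 0.0088 in subcutaneous tumours (n = 3) and 0.318 in pre-injected cells. In the metabolic screen it was 0.982 ± 0.00229 in lungs and 0.970 ± 0.0019 in livers (n = 5 each), 0.964 ± 0.0142 in subcutaneous tumours (n = 2) and 0.933 in pre-injected cells, whereas the plasmid stood at 0.374. There, 90% of the signal lay in 21205 guides of the plasmid, 2722 guides of the pre-injected cells, and on average 963 guides in subcutaneous tumours, 781.6 in livers and 307.2 in lungs. ES-2 mini lungs reached 0.706 ± 0.0905, beside 0.399 ± 0.00828 in subcutaneous tumours and 0.372 ± 0.0321 in livers (n = 4 each). SKHEP-1 lungs stood at 0.590 ± 0.128 beside 0.464 ± 0.0919 in subcutaneous tumours, 0.327 ± 0.0401 in culture and 0.282 ± 0.0149 in pre-injected cells (n = 4 each). No difference passed 0.05 after adjustment over 12 comparisons by exact two-sided permutation tests. Lungs against livers gave adjusted p = 0.0686 in all 3 ES-2 screens, with an unadjusted p of 0.0179 (phosphatase), 0.00794 (metabolic) and 0.0286 (mini), each the smallest that a test without pairs allows. Within the 4 pairs of the ES-2 mini screen, a test chosen after the data were seen, lungs exceeded livers in 4 of 4 (unadjusted p = 0.125, the smallest possible, adjusted p = 0.190), and subcutaneous tumours likewise. Lungs against subcutaneous tumours gave adjusted p = 0.171 (phosphatase), 0.0952 (metabolic), 0.0686 (ES-2 mini) and 0.190 (SKHEP-1), where the smallest unadjusted p possible was 0.1, 0.0476, 0.0286 and 0.0286 by the exact test. SKHEP-1 subcutaneous tumours against pre-injected cells gave adjusted p = 0.0686, cultured against pre-injected cells 0.190, and livers against subcutaneous tumours 0.768 (phosphatase), 0.364 (metabolic) and 0.309 (ES-2 mini) by the same exact test. Over control guides alone metabolic lungs exceeded livers by 0.00618 (unadjusted p = 0.246) beside 0.0124 over all guides (0.00794), and subcutaneous tumours by 0.0171 (0.238) beside 0.0186 (0.0476). The sign of the liver difference in the phosphatase screen turned over control guides alone, and that of lungs against livers in the metabolic screen turned for the share of guides at a value of 0.

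**Figure D1:**
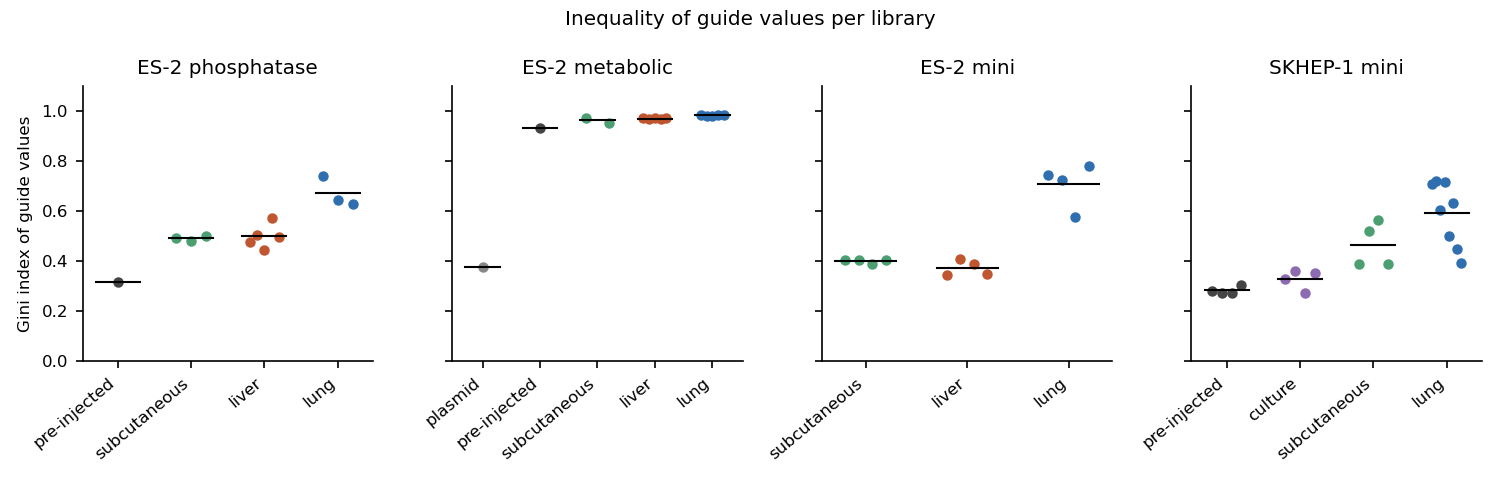
Gini index of guide values (vertical axis, no unit) for each library, by group and screen; points are libraries (both parts of each SKHEP-1 lung are drawn) and bars are means over the points. Lungs have the highest mean in each screen, 0.671, 0.982, 0.706 and 0.590.

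The liver comparison of the phosphatase screen asked which phosphatase knockouts were lost or gained in livers relative to subcutaneous tumours. No gene passed the threshold. The lowest p belonged to PPP1R11, an inhibitor of protein phosphatase 1, at a log2 fold change of -1.03 ± 0.263 (SE, n = 5 and 3, adjusted p = 0.307 by limma with Benjamini-Hochberg), with all 4 guides lower and all 5 livers below all 3 subcutaneous tumours. Next among lower values stood the receptor-type tyrosine phosphatase PTPRH (-0.68), PPP2CB (-0.53) and PPP1CC (-0.48), catalytic subunits of protein phosphatases 2A and 1, and the inorganic pyrophosphatase PPA1 (-0.66). Among higher values stood the lipid phosphate phosphatases PLPP3 (0.54, PPAP2B in the deposited table) and PLPP2 (0.41, deposited as PPAP2C), PGP (0.37), the myotubularin MTMR10 (0.37) and MFN1 (0.39), with adjusted p of 0.785 for these 5. In the list named for catalytic and scaffold subunits of PP1 and PP2A, 12 of 14 measured members had values below 0 with a median of -0.25. Of them 0 passed the threshold (0 adjusted over the list alone). The list has more members than PP1 and PP2A have such subunits, so its values are not theirs alone. The camera test of that list gave adjusted p = 0.0842, and adjusted p = 0.908 with an estimated correlation. By limma 16 genes had an unadjusted p under 0.05, and edgeR and rank aggregation also called 0 genes. Without subcutaneous replicate 3, 1 gene passed.

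In phosphatase lungs, 12 genes passed against subcutaneous tumours, 5 lower and 7 higher. ENTPD2, an ectonucleotidase (chromosome 9, 137048107 to 137054061), fell by 1.47 ± 0.264 on the log2 scale (n = 3 and 3, adjusted p = 0.0088), and PPA1, which hydrolyses pyrophosphate (chromosome 10, 70202835 to 70233429), fell by 1.26 ± 0.268 (adjusted p = 0.028), both with 4 of 4 guides lower. The acylphosphatase ACYP1 (-0.84), the tyrosine phosphatase PTPN14 (-0.87), known as a brake on YAP signalling, and SET (-0.90), an inhibitor of PP2A, were also lower. The 7 higher genes were PLPP2 (1.04 ± 0.236, adjusted p = 0.0338), the PP1 regulatory subunit PPP1R16A (0.97), the tyrosine phosphatases PTPN3 (0.99) and PTPN23 (0.85), the myotubularin MTMR11 (1.16), DUSP29 (1.17, deposited as DUPD1) and CDC25B (1.09), which activates cyclin-dependent kinases. For each of the 12, all 3 lungs lay beyond all 3 subcutaneous tumours, which chance gives for 10% of genes with 3 against 3. By list, 3 of 21 non-receptor tyrosine phosphatases passed (1 lower, 2 higher, 4 adjusted over the list alone), 1 of 34 myotubularins and phosphoinositide phosphatases (4 over the list alone), 1 of 33 dual-specificity phosphatases (0 over the list alone) and 1 of 15 lipid phosphatases (1 over the list alone). Lipid phosphatases had 12 members above 0 with a median of 0.29, and no list passed camera (lowest adjusted p = 0.328).

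The tools differed on the phosphatase lungs. By limma 65 genes had an unadjusted p under 0.05; edgeR called 89 genes (8 lower, 81 higher) and rank aggregation called 0. Centring on control guides called 22 genes, 14 lower and 8 higher, and scaling to the same total, which put the median of all genes at -0.79, called 169 genes, all lower. Without subcutaneous replicate 1 no gene passed, and without lung replicate 3, 37 did. Leaving out subcutaneous replicate 2 gave 2 genes and leaving out lung replicate 1 gave 7.

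Against livers, 7 knockouts were higher in phosphatase lungs and 0 were lower past the threshold. NUDT11, which hydrolyses inositol pyrophosphates (chromosome X, 51490011 to 51496592), rose by 1.17 ± 0.216 (n = 3 and 5, adjusted p = 0.0122) and passed in all 8 fits that left out 1 library, whereas PPP1R16A passed in 7, PPP2R5C in 5, MTMR11, MTMR6 and PTPN3 in 3 each and PPP2CA in 1. PPP1R16A rose by 1.08 ± 0.213 (adjusted p = 0.0124), MTMR11 by 1.15, MTMR6 by 0.96, PTPN3 by 0.89 and the PP2A subunits PPP2CA (catalytic) and PPP2R5C (regulatory) by 0.99 and 0.90, with adjusted p of 0.0261 to 0.0408. Every lung lay above every liver for 6 of the 7, and 2 of 3 lungs did for PPP2CA. The lowest p among lower values belonged to ENTPD2 (-0.86 ± 0.236, adjusted p = 0.0688), MTMR8 (-0.68), PTPN22 (-0.68), MTMR10 (-0.66) and the nucleotidase CANT1 (-0.79), none past the threshold. Myotubularins and phosphoinositide phosphatases had 2 of 34 members higher (4 adjusted over the list alone) with a median of 0.25, and no list passed camera (lowest adjusted p = 0.721). By limma 62 genes had an unadjusted p under 0.05; edgeR called 121 genes, 1 lower and 120 higher, and rank aggregation 0. Centring on control guides called 11 genes, 1 lower and 10 higher, while scaling to the same total (median of all genes -0.76) called 170 genes, all lower. Leaving out 1 library gave 1 gene without liver replicate 3 and 30 without lung replicate 3. It gave 19 without lung replicate 2, 2 without lung replicate 1 or liver replicate 5, and 3 without liver replicate 1 or liver replicate 2.

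Subcutaneous phosphatase tumours against the single pre-injected library gave no gene past the threshold. The lowest p values were for PPP6C (-1.60 ± 0.407), PPP4C (-1.42) and PPP3R1 (-1.14 ± 0.298), which encode the catalytic subunits of protein phosphatases 6 and 4 and the regulatory subunit of calcineurin, each with adjusted p = 0.185 (n = 3 and 1). After centring on control guides these 3 had adjusted p of 0.0373, 0.0462 and 0.0462. MTMR10 (-1.10) and GET3 (-0.96, deposited as ASNA1), which targets tail-anchored proteins to membranes, also lay low. PTPRH (1.01), MTMR14 (1.12), PPM1D (0.77), the proton pump subunit ATP6V0E1 (1.05) and INPPL1 (0.96) lay high, with adjusted p of 0.185 to 0.319. Of the 14 members of the list named for PP1 and PP2A subunits, 3 passed adjusted over the list alone and 0 over all genes. The list median was 0.19 and its mean -0.19, and camera gave adjusted p = 0.537. By limma 31 genes had an unadjusted p under 0.05, edgeR called 0 and rank aggregation 1, and scaling to the same total called 3 (median of all genes -0.38).

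Many guides behind the metabolic gene scores stood near the plasmid library in animals. Of the 13354 guides used, 59.5% to 67.7% in livers, 61.2% and 65.6% in subcutaneous tumours and 69.7% to 77.0% in lungs lay within 2-fold of their plasmid value, beside 21.4% in the pre-injected cells. The median ratio to the plasmid over these guides was 4.89 in the pre-injected cells and 0.996 to 1.22 in animals.

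In the metabolic screen, 1 of 2618 genes passed in livers against subcutaneous tumours. Knockouts of ULK1, the kinase that starts autophagy (chromosome 12, 131894622 to 131923150), were lower by a log2 fold change of -1.81 ± 0.288 (n = 5 and 2, adjusted p = 0.0356), in 3 of 3 guides and in all 5 livers. Not past the threshold were PGM3 (-1.82), an enzyme of UDP-GlcNAc synthesis, the dipeptidase DPEP1 (-1.52) and ISCA2 (-1.09), which builds iron-sulfur clusters, each with adjusted p = 0.0727. Higher values not past it were NUDT11 (2.18), the mitochondrial carrier SLC25A35 (1.56), ATP6V0E1 (1.51), CYP2F1 (1.25) and the acid sphingomyelinase SMPD1 (1.04), with adjusted p of 0.169 to 0.181. No list passed camera (lowest adjusted p = 0.259), and the 14 genes of PUFA activation, desaturation and phospholipid incorporation had a median of -0.18, with 8 below 0 and 0 past the threshold over all genes or adjusted over the list alone. By limma 290 genes had an unadjusted p under 0.05. The count was 59 by edgeR (57 lower, 2 higher), 0 by rank aggregation, 0 without the guide filter and 5 after centring on control guides. ULK1 passed in 1 of the 7 fits that left out 1 library; the count was 13 without subcutaneous replicate 3, 2 without liver replicate 1, and 0 without subcutaneous replicate 2 or without liver replicate 2, 3, 4 or 5.

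Metabolic lungs against subcutaneous tumours gave 155 genes, 153 lower and 2 higher. Across genes the change had a rank correlation of -0.357 with the pre-injected score, so genes that started higher tended to fall more. The lowest adjusted p was shared by the melanin enzyme TYR (-2.71 ± 0.357), DPEP1 (-2.10 ± 0.290) and ELOVL1 (-2.89 ± 0.424), which elongates saturated and monounsaturated very long-chain fatty acids (chromosome 1, 43363401 to 43368011), at 0.00278 (n = 5 and 2). SLC10A7 (-2.34), PGM3 (-2.12), AWAT1 (-2.04), the fucosyltransferase FUT6 (-2.03), SPTLC1 (-2.01), a subunit of the first enzyme of sphingolipid synthesis, GNPDA2 (-1.997) and the mitochondrial PEP carboxykinase PCK2 (-1.94) completed the 10 largest decreases, with adjusted p of 0.00377 to 0.0336. In each of these 10 genes all 5 lungs lay below both subcutaneous tumours. The 2 higher genes were the phospholipase PLB1 (1.07 ± 0.245, adjusted p = 0.0213) and the fucosyltransferase FUT2 (1.19 ± 0.325, adjusted p = 0.0441), which passed in 6 and 0 of the 7 fits that left out 1 library. CTPS1 (0.68), UGT2B10 (0.69) and ETNK2 (1.11) were highest below the threshold.

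Lipid genes stood among the lower knockouts of metabolic lungs, where 71.6% of all genes lay below 0 against subcutaneous tumours. Of 14 genes of PUFA activation, desaturation and phospholipid incorporation, 3 were lower past the threshold, 5 adjusted over the list alone, and 13 lay below 0 with a median of -0.69. These were LPCAT3 (-0.98 ± 0.227, adjusted p = 0.0219; chromosome 12, 6976185 to 7018476), which puts polyunsaturated acyl chains into phospholipids, LPCAT1 (-1.06 ± 0.238, adjusted p = 0.0201; chromosome 5, 1461427 to 1523960), which favours saturated chains, and MBOAT1 (-1.16 ± 0.301, adjusted p = 0.034; chromosome 6, 20099684 to 20212469), another acyltransferase of lysophospholipids. All 6 guides of LPCAT3 were lower, and all 5 lungs lay below both subcutaneous tumours for each of the 3. LPCAT1 passed in 6, LPCAT3 in 5 and MBOAT1 in 3 of the 7 fits that left out 1 library. Camera did not separate the list from other genes (adjusted p = 0.259; adjusted p = 0.673 with an estimated correlation). Of 14 genes of mitochondrial beta-oxidation 3 were lower (4 adjusted over the list alone, 12 below 0), namely ACADM (-1.57), HADHB (-1.32) and ETFA (-1.31). Among 9 genes of fatty acid synthesis ELOVL1 and the desaturase SCD5 (-1.12) were lower (4 over the list alone, 7 below 0). Among 20 genes of heparan sulfate synthesis EXTL3 (-1.54), PAPSS2 (-1.47) and NDST2 (-1.21) were lower (3 over the list alone). DHRS7B, the reductase of ether lipid synthesis (-1.36, adjusted p = 0.0166; chromosome 17, 21126964 to 21191420), was the only one of 7 ether lipid genes to pass (1 over the list alone), and COQ10A and COQ10B were 2 of 11 coenzyme Q genes (3 over the list alone). Of 13 genes of glutathione, selenium and ferroptosis defence, and of 6 auxiliary enzymes of unsaturated fatty acid beta-oxidation, 0 passed over all genes or over the list alone.

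The vacuolar ATPase, the proton pump of lysosomes, was the only list past camera in that comparison. Its 13 measured genes had a median of 0.16 with 9 above 0, while the median of all genes was -0.28, and 0 passed by themselves over all genes or adjusted over the list alone. The list had adjusted p = 0.0101 over 48 tests, and adjusted p = 0.356 with an estimated correlation. The positive median is relative to the deposited scaling, since scaling to the same total moved the median of all genes to -1.003.

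ACSL4, the acyl-CoA synthetase in the series title, which activates long polyunsaturated fatty acids (chromosome X, 109641335 to 109733257), did not pass in lungs or livers of the metabolic screen. Its log2 fold change was -0.69 ± 0.325 in lungs (unadjusted p = 0.0503 by limma, adjusted p = 0.215; 6 of 8 guides lower, 2 of 5 lungs below both subcutaneous tumours) and -0.58 ± 0.325 in livers (adjusted p = 0.565; 4 of 8 guides lower). The values rested on which subcutaneous tumour was kept: without replicate 2 they were -0.01 in lungs (adjusted p = 0.992) and 0.09 in livers, and without replicate 3 they were -1.37 in lungs (adjusted p = 0.0297) and -1.26 in livers (adjusted p = 0.0992). The largest gap between the 2 tumours was in 1 of the 8 guides, at 1671 in replicate 2 and 59.7 in replicate 3. That guide stood at 40.6 to 67.9 in livers and lungs. Scaling to the same total gave -1.41 in lungs (adjusted p = 0.00349). That scaling also moved the median of all genes down, as given above, so the call is not particular to ACSL4. LPCAT3 in lungs had -0.81 without subcutaneous replicate 2 (adjusted p = 0.26) and adjusted p = 0.107 after centring on control guides. The peroxisomal ether lipid enzymes FAR1 (-0.66), AGPS (-0.25) and GNPAT (-0.16) and the auxiliary enzymes ECH1 (0.25) and ECI1 (-0.08) were not past the threshold in lungs, and neither were LPCAT3 (-0.30), GNPAT (0.65), FAR1 (0.44), ECH1 (0.28), AGPS (0.12) and ECI1 (-0.09) in livers. GPX4, which reduces lipid peroxides, was not tested because 8 of its 10 guides lay below 10 in the pre-injected cells.

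**Figure D2:**
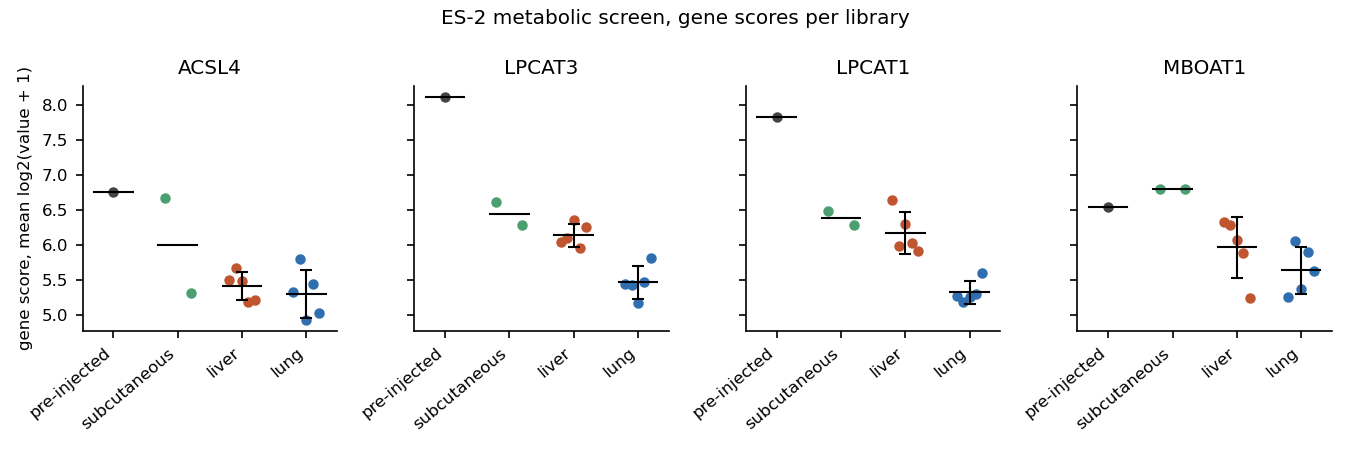
Gene score (vertical axis, mean over guides of log2(value + 1)) of ACSL4, LPCAT3, LPCAT1 and MBOAT1 in each library of the ES-2 metabolic screen; points are libraries, bars are means, and error bars are SD where a group has over 2 libraries. The 2 subcutaneous tumours stand at 6.67 and 5.32 for ACSL4, and all 5 lungs lie below both of them for LPCAT3, LPCAT1 and MBOAT1.

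The excess of lower genes in metabolic lungs was shared by control guides. By limma 610 genes had an unadjusted p under 0.05, and 22.04% of genes were lower at that p, beside 16.5% of 70 pseudo-genes made of 5 control guides each (mean of 100 draws). The count was 365 by edgeR (348 lower, 17 higher), 0 by rank aggregation, 52 with the median over guides, 50 without the guide filter and 73 after centring on control guides (68 lower, 5 higher), and scaling to the same total called 1440 genes, all lower. It was 25 without subcutaneous replicate 2 and 248 without lung replicate 5. It was 79, 78 and 97 without lung replicates 1, 3 and 4.

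**Figure D3:**
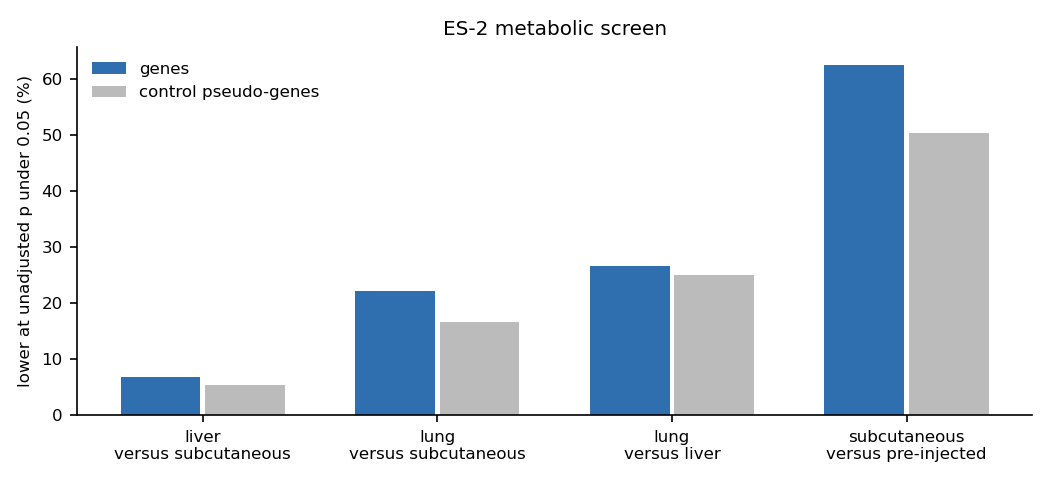
Share of genes and of pseudo-genes made of control guides (vertical axis, percent) that were lower at an unadjusted p under 0.05 in each comparison of the ES-2 metabolic screen. Lungs against livers give 26.6% of genes and 25.03% of pseudo-genes, and subcutaneous tumours against pre-injected cells 62.5% and 50.3%.

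The 2 organs differed in the metabolic screen, with 222 genes past the threshold in lungs against livers, 221 lower and 1 higher. Of all genes, 75.1% lay below 0 there. Genes with a higher pre-injected score tended to fall more, with a rank correlation of -0.517 between that score and the change. Single genes were not matched on that score. The tRNA dihydrouridine synthase DUS3L (-1.63 ± 0.198; chromosome 19, 5785140 to 5791163) and the carbonyl reductase CBR1 (-1.73 ± 0.216) had the lowest adjusted p, 0.00096 (n = 5 and 5), with 4 of 4 guides lower and every lung below every liver. The other largest decreases were NME3 (-1.96), the calcium channel subunits ORAI3 (-1.92) and CATSPER3 (-1.82), STS (-1.72), FOLR2 (-1.68), FN3K (-1.66), ALAS2 (-1.62), which starts haem synthesis in erythroid cells, and LCAT (-1.57), with adjusted p of 0.00288 to 0.0279. GUSB, a lysosomal glucuronidase, was the 1 higher gene (0.71 ± 0.190, adjusted p = 0.0346, kept in 3 of 10 fits without 1 library), followed below the threshold by CYBB (0.54), GLRX5 (0.61), PLB1 (0.60) and CTPS1 (0.50). Lower in the PUFA list were LPCAT1 (-0.85), which favours saturated chains, LPCAT3 (-0.68 ± 0.172, adjusted p = 0.0284 by limma) and ACSL5 (-0.99). Lists fixed in advance held these 3 of 14 members of the PUFA list lower (5 adjusted over the list alone, 13 below 0). They held 2 of 7 ether lipid genes (DHRS7B -1.37, CHPT1 -1.08; 3 over the list alone, 7 below 0), 4 of 15 lipid phosphatases (PLPP2 -1.44, PLPPR2 -0.93, LPIN3 -0.89, PLPP1 -0.86; 4 over the list alone) and 4 of 20 heparan sulfate genes (PAPSS2 -1.18, NDST2 -1.14, EXTL3 -1.06, EXT2 -0.79; 5 over the list alone). Camera gave adjusted p = 0.0714 for the PUFA and the ether lipid lists, and adjusted p = 0.339 for both with an estimated correlation. The vacuolar ATPase had a median of 0.23, with 9 of 13 genes above 0 (adjusted p = 0.00136 over 24 lists; adjusted p = 0.112 with an estimated correlation). ACSL4 (-0.11, adjusted p = 0.81), FAR1 (-1.10, adjusted p = 0.0988), GNPAT (-0.81), AGPS (-0.37), ECH1 (-0.02) and ECI1 (0.01) did not pass.

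By limma 730 genes of lungs against livers had an unadjusted p under 0.05, and 26.6% of genes were lower at that p, beside 25.03% of control pseudo-genes. The count was 84 by edgeR (81 lower, 3 higher), 0 by rank aggregation, 80 with the median over guides, 54 without the guide filter (48 lower, 6 higher) and 46 after centring on control guides (36 lower, 10 higher). Scaling to the same total, with a median of all genes at -0.85, called 1754 genes, all lower. Leaving out liver replicate 2 gave 61 genes and leaving out lung replicate 5 gave 375. The count was 79, 63 and 84 without lung replicates 1, 3 and 4, and 120 and 83 without liver replicates 1 and 3.

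In subcutaneous tumours against the single pre-injected library, 1506 of 2618 metabolic genes were lower and 13 higher past the threshold. With 1 library in that arm its own variation is not separated from growth, and the guide filter used the same library. The fatty acid isomerases ECI1 (-4.48 ± 0.362, adjusted p = 6.21e-06; chromosome 16, 2239402 to 2251587) and ECH1 (-3.68 ± 0.380, adjusted p = 1.53e-05; chromosome 19, 38815422 to 38831794), which let double bonds enter beta-oxidation, were among the lowest (n = 2 and 1). The 10 largest decreases were ST8SIA1 (-5.28), PDE6C (-4.70), NME3 (-4.62), ECI1, ZC3H12A (-4.36), the choline kinase CHKA (-4.08), ACSBG2 (-4.03) and ACSF2 (-4.02), which activate fatty acids, fatty acid synthase FASN (-3.98) and B3GNT4 (-3.95). Complex I of the respiratory chain had 28 of 36 genes lower and 1 higher (30 adjusted over the list alone), with NDUFA12 (-2.87), NDUFC1 (-2.49) and NDUFA3 (-2.44) lower and NDUFS4 (1.18) higher. Complexes III, IV and V had 23 of 36 lower (23 over the list alone), heparan sulfate synthesis 14 of 20 (14), the TCA cycle 10 of 18 (10), mitochondrial beta-oxidation 9 of 14 (10), the PUFA list 9 of 14 (9), ether lipid synthesis 4 of 7 (4), auxiliary beta-oxidation enzymes 4 of 6 (4) and glutathione and ferroptosis defence 6 of 13 (6). LPCAT3 (-1.67, adjusted p = 0.000963) and AGPS (-1.35, adjusted p = 0.0116) were lower, while ACSL4 (-0.76, adjusted p = 0.18), GNPAT (-1.39, adjusted p = 0.0801) and FAR1 (-1.14, adjusted p = 0.224) did not pass. The 10 largest increases ran from 0.97 to 1.68 and included AKR1C4 (1.68), SHMT1 (1.13), COASY (1.08), and the proton pump subunits ATP6V1F (1.02) and ATP6V1C1 (0.97). Only the vacuolar ATPase passed camera among 24 lists, with a median of 0.10 (1 lower, ATP6V0A2 at -1.45, and 2 higher; 3 over the list alone), adjusted p = 6e-08, and adjusted p = 0.00862 with an estimated correlation.

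That lower side was also seen in control guides. The median of all genes was -1.24 with 91.7% below 0, the mean of control guides was -0.93, and 62.5% of genes and 50.3% of control pseudo-genes were lower at an unadjusted p under 0.05. After centring on control guides 454 genes passed, 347 lower and 107 higher; without the guide filter 630 passed, 304 lower and 326 higher; by edgeR 581 (574 lower, 7 higher); and by rank aggregation 0. ACSL4 stood at 0.17 after that centring.

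In the ES-2 mini screen the replicate number paired the samples, and the fit with it as a block is given beside the fit without. Control guides had medians of 1746 to 2390 in number 1, 748 to 842 in number 2, 5606 to 5881 in number 3 and 1414 to 1513 in number 4. The fit without the block counts this offset as spread between samples, and centring on control guides called 1 gene in lungs and 0 in the other 2 comparisons. In lungs against subcutaneous tumours 0 genes passed without the block and 8 with it, 7 higher and 1 lower, each in 4 of 4 pairs. PPP2R1A, the scaffold subunit of PP2A (chromosome 19, 52190052 to 52229518), stood at 2.55 ± 0.391 with the block (n = 4 pairs, adjusted p = 0.000972; adjusted p = 0.414 without it). Above 0 with the block were also the receptor phosphatase PTPRG (1.63), the proton pump subunits ATP6V1B2 (1.58) and ATP6V1H (1.36) and the PP2A regulatory subunit PPP2R5B (1.39), and, chosen after their values were seen, the mitochondrial fusion protein MFN2 (1.22) and the cholesterol hydroxylase CH25H (0.92), with adjusted p of 0.00329 to 0.0427. NMNAT1, which makes nuclear NAD (chromosome 1, 9942923 to 9996892), was lower at -1.11 with the block (adjusted p = 0.0261). It stood at 0.31 by edgeR, which was fitted without the block. In the simulated ES-2 mini design that edgeR fit recovered 0 of 5 changed genes at either fold. Without the block limma gave 1 gene at an unadjusted p under 0.05, and edgeR called 0 and rank aggregation 1. Without replicate number 1, 2, 3 or 4 the blocked count was 2, 6, 7 or 4. Scaling to the same total, which moved the median of all genes from 0.27 to -1.12, called 56 genes, 55 lower and 1 higher, and put PPP2R5B, ATP6V1H, MFN2 and CH25H below 0.

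Genes named in the primary screens were lower or higher in ES-2 mini lungs by values that did not pass with or without the block. ACSL4 stood at -0.15 in lungs against subcutaneous tumours (2 pairs lower, 2 higher; adjusted p = 0.863 with the block), 0.08 in livers and -0.23 in lungs against livers; scaled to the same total it was -1.54 in lungs (adjusted p = 0.0223) and -1.72 in lungs against livers (adjusted p = 0.0144). ELOVL1 was at 0.98, PTPN22 at 0.86, PPP2CA at 0.89, ENTPD2 at 0.55, PPA1 at 0.50, and B3GNT4 at -0.86 (adjusted p = 0.0539 with the block, 4 of 4 pairs lower). FOXO1 (-0.84), PPP2R5C (-0.61) and PTPRJ (-0.56) were the other low values. ELOVL1, ENTPD2 and PPA1 were lower past the threshold in lungs against subcutaneous tumours of the primary screens, so their direction was opposite here. Over all shared genes the sign was the same for 9 of 24 with phosphatase lungs and 26 of 65 with metabolic lungs. The median of all genes also differed, at -0.28 in metabolic and 0.27 in ES-2 mini lungs.

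Livers against subcutaneous tumours gave 0 genes in the ES-2 mini screen with and without the block. PPP2R1A (1.26), PTPRG (0.77), MFN2 (0.59) and ATP6V1B2 (0.58) had low p among higher values, and NMNAT1 (-0.82), PPP2R5C (-0.75), CDC25B (-0.65), PGM3 (-0.55) and ELOVL1 (-0.47) among lower ones, with adjusted p = 0.999 for all by limma and of 0.564 to 0.997 with the block. At an unadjusted p under 0.05 there were 0 genes without the block and 5 with it; edgeR called 0 and rank aggregation 2. Lungs against livers also gave 0 genes with and without the block (0 and 19 genes at an unadjusted p under 0.05; edgeR 0, rank aggregation 1). The highest were ELOVL1 (1.44), PPP2R1A (1.29), PPP2R5B (1.26), ATP6V1B2 (1.00) and ATP6V1H (0.93), and the lowest FOXO1 (-0.58), B3GNT4 (-0.46), KCNH3 (-0.33), SLC10A7 (-0.30) and NMNAT1 (-0.30). Scaling to the same total moved the median of all genes there to -1.21 and called 64 genes, all lower.

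SKHEP-1 lungs against subcutaneous tumours gave 0 genes past the threshold. The lowest p values belonged to MSRA (0.69 ± 0.213), a repair enzyme of oxidised methionine, MTMR6 (0.45), PDE2A (0.43), the ATP-gated channel P2RX7 (0.43) and PTPN3 (0.34), and to the transcription factor FOXO1 (-0.59 ± 0.186), SMPDL3B (-0.42), PPP2R5C (-0.51) and PTPRE (-0.56), each with adjusted p = 0.238 (n = 4 and 4), and AGPAT9 (-0.29, adjusted p = 0.417). ACSL4 was at 0.19 ± 0.181 (adjusted p = 0.567), higher in 4 of 4 replicate numbers. By limma 14 genes had an unadjusted p under 0.05; edgeR called 3, all higher, and rank aggregation 0, and scaling to the same total called 5 (median of all genes -0.36) and put ACSL4 (-0.31), MTMR6, PDE2A, P2RX7 and PTPN3 below 0.

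After culture for 7 doublings 5 SKHEP-1 knockouts were lower past the threshold than in pre-injected cells, although a chance split was not excluded, as given below. NMNAT1 fell by 0.90 ± 0.184 and PPP2R1A by 0.83 ± 0.176 (both adjusted p = 0.00927, n = 4 and 4), in 4 of 4 guides and with all 4 cultures below all 4 pre-injected samples. CNEP1R1 (-0.56, adjusted p = 0.0175), a partner of the lipin phosphatase, MECR (-1.31, adjusted p = 0.0364), the reductase of mitochondrial fatty acid synthesis, and PPP2CA (-0.85, adjusted p = 0.0364) followed. ACSL4 was at -0.51 ± 0.181 (adjusted p = 0.123, 4 of 4 guides lower). The highest values, PTPN14 (0.28), PTPRG (0.39), PTPN3 (0.24), CH25H (0.25) and SCD5 (0.19), did not pass. By limma 13 genes had an unadjusted p under 0.05; edgeR called 0 and rank aggregation 6. The count ran from 0 without pre-injected replicate 4 to 15 without culture replicate 3. It was 1, 2 and 3 without culture replicates 1, 2 and 4, and 3, 2 and 2 without pre-injected replicates 1, 2 and 3.

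Subcutaneous SKHEP-1 tumours gave 0 genes against pre-injected cells. SMPDL3B (0.62), FOXO1 (0.59), PTPRG (0.65), PPP1R16A (0.70) and CH25H (0.59) were highest and CNEP1R1 (-0.45) lowest by p, all with adjusted p = 0.109, followed by PPP2R1A (-0.46), NMNAT1 (-0.43), ACSL4 (-0.36, adjusted p = 0.376) and MECR (-0.55). CNEP1R1 had adjusted p = 0.024 after centring on control guides. By limma 15 genes had an unadjusted p under 0.05, edgeR called 0 and rank aggregation 1, and scaling to the same total called 3 (median of all genes -0.38); without subcutaneous replicate 1 limma called 3.

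**Figure D4:**
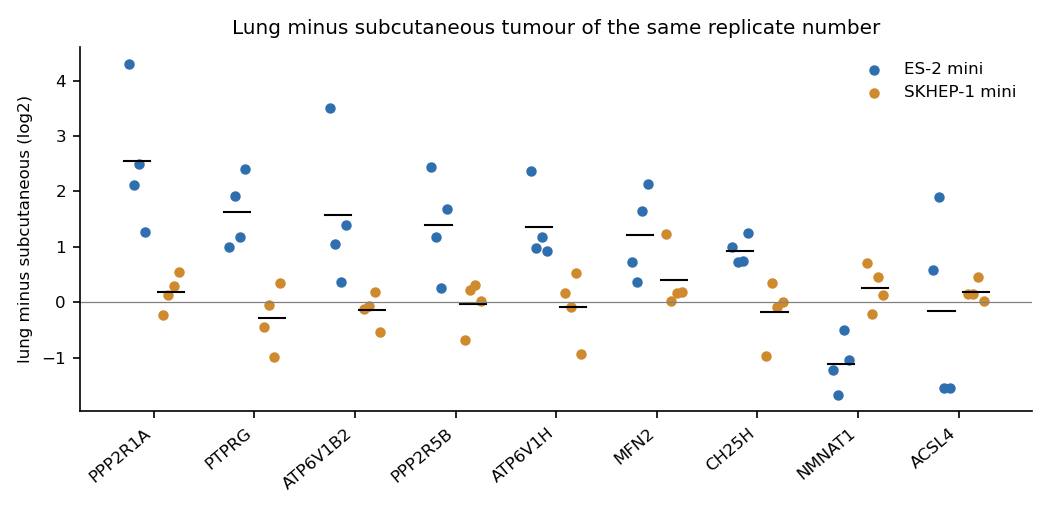
Gene score of lungs minus that of the subcutaneous tumour with the same replicate number (vertical axis, log2) for 9 genes in the ES-2 and SKHEP-1 mini screens; points are replicate numbers and bars are means. The ES-2 mean is 2.55 for PPP2R1A, -1.11 for NMNAT1 and -0.15 for ACSL4, and the SKHEP-1 mean of ACSL4 is 0.19.

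Fold changes in livers and in lungs were correlated across genes, which are not independent replicates and share the subcutaneous tumours. Pearson's r was 0.551 in the phosphatase screen beside 0.560 (95% range 0.422 to 0.664) simulated for unchanged groups, and the covariance was 0.0595 beside 0.0386. In the metabolic screen r was 0.643 beside 0.715 (0.679 to 0.743) and the covariance 0.136 beside 0.0851. In the ES-2 mini screen r was 0.746 beside 0.506 (0.204 to 0.752) and the covariance 0.131 beside 0.0643; with the subcutaneous tumours split between the organs r was 0.362 to 0.463 over 6 splits. Between screens or cell lines, 7 relations gave r from -0.201 to 0.175 over 24 to 99 shared genes, with adjusted p from 0.567 to 0.841 by 100000 permutations.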

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

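The tests of clone loss, of the deposited scaling and of splits after centring, and the shares of guides near the plasmid, were chosen only after the lung results were seen, and the other tests were written down before. In the metabolic screen the effects in the 2 organs differed by a direct test for 222 genes, 221 of them lower in lungs than in livers. One technical explanation is that few clones reach or outgrow in lungs, which lowers most guides whatever they target. It predicts that pseudo-genes of control guides fall as often as genes, and 25.03% of them were lower at an unadjusted p under 0.05 beside 26.6% of genes, so clone loss may account for most of the lower side. The Gini index over control guides alone, however, was higher in lungs by only 0.00618 (unadjusted p = 0.246), so that measure did not show a greater loss of control guides. Lungs also had more guides within 2-fold of the plasmid (69.7% to 77.0% of those used) than livers (59.5% to 67.7%), and whether plasmid DNA contributed was not tested. The other technical explanation, a scaling that puts lung libraries too low, stays undecided: after centring on control guides 36 of 46 called genes (78.3%) were still lower. Effects of single knockouts that differ between the organs stay open as the biological explanation, since no test here separates them from clone loss for a given gene.

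In the phosphatase screen the effects in lungs and livers differed for 7 genes, all higher in lungs. Over the 56 ways to split those 8 libraries into 3 and 5, only the real split (count of 1) gave 7 or more genes. The highest other gave 1, so a chance split is unlikely as the source. That share is the smallest that 56 splits allow, and such shares were not adjusted over the comparisons. Of 100 splits of the metabolic lungs and livers, drawn with the real one among them, again only 1 reached 222. The highest other gave 65, so a chance split is unlikely there too. The 12 genes of phosphatase lungs against subcutaneous tumours stood alone among 10 splits (1 of 10, highest other 0), which are too few. The same holds for the 8 genes of the ES-2 mini lungs with the block, alone among 8 swaps within replicate numbers (1 of 8, highest other 0). The 5 genes of SKHEP-1 cultures were reached by 4 of 35 splits with a highest of 10, so a chance split is not excluded. Counts of 0 were reached by every split, 56 of 56 for phosphatase livers and 35 of 35 for each of the SKHEP-1 lungs (highest other 2) and subcutaneous tumours (highest other 0). In the ES-2 mini screen, too, 35 of 35 splits reached the real 0 in livers, in lungs and in lungs against livers, and other splits gave up to 62, 50 and 54 genes, which points to a structure of the samples. The highest split parted replicate numbers 1 and 3 from 2 and 4 each time, as the scale of the control guides does (medians of 1746 to 5881 and of 748 to 1513). After centring on control guides the real split gave 0, 1 and 0 genes, and the highest other 0, 1 and 0.

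Single libraries far from the rest of their group were found in 27 of 434 tests of a highest or lowest value against its nearest neighbour, and chance gives about 1 in 20 groups. Phosphatase liver replicate 2 had 28.6 M recovered reads, the next liver 11.3 M. ES-2 mini subcutaneous replicate 3 had 2.92 M reads (next 0.806 M) and a Gini index of 0.387 (next 0.402), and in ES-2 mini liver replicate 2 the top guide took 4.34% of the signal (next 1.11%). Metabolic lung replicate 5 stood apart for 9 genes. Its gene score was highest for LCAT (9.09), PCK2 (7.86), STS (7.42), ACSBG2 (7.05), NDUFA12 (7.03), SLC25A35 (6.36), LPCAT1 (5.60) and AGPS (5.18), and lowest for CHKA (2.63). Metabolic lung replicate 2 was highest for ACSL5 (6.28) and lowest for PDE6C (3.27). Among metabolic livers, replicate 5 was lowest for GNPDA2 (7.08) and NDUFS3 (5.06), replicate 3 highest for FUT2 (7.51) and replicate 4 highest for ATP6V1F (5.13). Phosphatase liver replicate 4 was highest for MTMR14 (14.37) and DUSP29 (13.98), and replicate 5 for PPP1R16A (13.81). In the mini screens the values were 12.05 for ATP6V1B2 in ES-2 lung replicate 1 (highest) and 10.05 for ENTPD2 in ES-2 lung replicate 2 (lowest). Scores of the ES-2 mini screen carry the offset between replicate numbers. Among its lungs replicate 2 had the lowest median of control guides (748), so the low ENTPD2 value can come from that offset. In SKHEP-1 further values stood apart. They were 11.33 for AGPAT9 in SKHEP-1 lung replicate 3 (highest), 11.29 for SCD5 in SKHEP-1 lung replicate 1 (highest) and 9.01 for PPP2R1A in SKHEP-1 subcutaneous replicate 4 (lowest).

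A signal outside the comparisons lay in the plasmid library of the metabolic screen, where 8924 guides stood at 10 or more but below 10 in the pre-injected cells. PIK3CG, a phosphoinositide kinase chosen after its values were seen, moved in opposite directions in the 2 cell lines: lungs minus the subcutaneous tumour of the same number averaged 0.812 in the 4 ES-2 pairs and -0.218 in the 4 SKHEP-1 numbers, 1.03 apart. Every ES-2 value was above 0 and every SKHEP-1 value below 0, but the difference was not tested. It was 1 of 99 genes searched for this pattern, about the number that chance gives, and scaling to the same total put its ES-2 lungs at -0.579.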

How the results depend on the processing

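Control-guide centring, the guide minimum of 100, the block without each replicate number and sign changes within pairs were chosen after the data were seen, and the other alternatives were fixed before. Of the 123 calls of named genes, which leave out the 8 made only with the block in ES-2 mini lungs, a pseudocount of 10 kept 120, scaling to the same total 93, control-guide centring 85, the block 67, edgeR 64, the median over guides 59, no guide filter 56 and rank aggregation 4. Scaling to the same total called only lower genes in phosphatase and metabolic lungs, against subcutaneous tumours and against livers. Lower calls that it kept there are thus little evidence of stability. The guide minimum of 100 kept 53 of the 55 metabolic calls whose genes still had 3 guides. Leaving out 1 library kept 525 of 815. A call kept its direction in all but 4 cases by edgeR, 2 with the median over guides and 2 without the guide filter. Of the 8 calls made only with the block, edgeR, which was fitted without it, turned 1. Scaling to the same total turned 4, as given below. That scaling moved the median of all genes of that comparison below 0, as given above, so those 4 turns are not particular to the genes. For the results that changed, the cause was not tested. Depth per guide was lowest in the metabolic screen, where libraries without the plasmid had a median of 8 to 16 recovered reads per guide; the lowest mini libraries had 74 (SKHEP-1) and 605.5 (ES-2). The ES-2 mini screen has no guide filter to remove, since its pre-injected cells were not analysed here, and a comparison with 1 pre-injected library cannot leave it out. Where leaving out a library left 1 in a group, its spread was taken from the other groups, so the lone library is assumed to vary like them. Averaging the 2 parts of each SKHEP-1 lung before the log2 step changed no count. The diversity difference turned to -0.0345 over control guides for livers against subcutaneous tumours of the phosphatase screen (adjusted p = 0.295), and the share of guides at 0 gave -0.439 percentage points for metabolic lungs against livers (adjusted p of 1). Sign changes within the ES-2 mini pairs changed no diversity call. With an estimated correlation 0 lists of the metabolic screen passed against subcutaneous tumours. Below, livers and lungs stand against subcutaneous tumours, and subcutaneous tumours and cultures against pre-injected cells, unless another group is named.

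After scaling to the same total 169 genes passed in phosphatase lungs, 170 in phosphatase lungs against livers, 3 in phosphatase subcutaneous tumours, 4 in metabolic livers, 1440 in metabolic lungs and 1754 in metabolic lungs against livers. It also passed 56 genes in ES-2 mini lungs, 64 in ES-2 mini lungs against livers, 5 in SKHEP-1 lungs, 3 in SKHEP-1 subcutaneous tumours and 2 in SKHEP-1 cultures. That scaling turned the sign of CTPS1 -0.0590, UGT2B10 -0.0504 and ECH1 -0.470 in metabolic lungs, and CYBB -0.0464, PLB1 -0.0137, CTPS1 -0.111 and ECI1 -0.582 in metabolic lungs against livers. It did so for PPP2R5B -0.00362, ATP6V1H -0.0234, MFN2 -0.172, CH25H -0.465, PIK3CG -0.579, ENTPD2 -0.835 and PPA1 -0.892 in ES-2 mini lungs, and ELOVL1 -0.0436, PPP2R1A -0.195, PPP2R5B -0.224, ATP6V1B2 -0.489 and ATP6V1H -0.552 in ES-2 mini lungs against livers. The same held for MTMR6 -0.0567, PDE2A -0.0726, P2RX7 -0.0701, PTPN3 -0.158, ACSL4 -0.313 and PPA1 -0.465 in SKHEP-1 lungs. After centring on control guides 22 genes passed in phosphatase lungs, 11 in phosphatase lungs against livers, 3 in phosphatase subcutaneous tumours, 5 in metabolic livers and 73 in metabolic lungs. It also passed 46 genes in metabolic lungs against livers, 454 in metabolic subcutaneous tumours, 1 in ES-2 mini lungs and 1 in SKHEP-1 subcutaneous tumours. That centring turned the sign of AGPS 0.00776, GNPAT 0.0948 and ECI1 0.176 in metabolic lungs, and ACSL4 0.161 and ECH1 0.243 in metabolic lungs against livers. It did so for ACSL4 0.173 in metabolic subcutaneous tumours. With a pseudocount of 10, 7 genes passed in metabolic livers. The larger pseudocount turned the sign of ECI1 -0.0345 in metabolic lungs against livers.

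By edgeR on summed reads 89 genes passed in phosphatase lungs, 121 in phosphatase lungs against livers, 59 in metabolic livers and 365 in metabolic lungs. It also passed 84 genes in metabolic lungs against livers, 581 in metabolic subcutaneous tumours, 3 in SKHEP-1 lungs and 0 in SKHEP-1 cultures. The edgeR value turned the sign of ECI1 0.441 in metabolic livers, and FUT6 0.668 and ECI1 0.456 in metabolic lungs. It did so for LPIN3 0.677, COX15 0.347 and ACSL4 0.0784 in metabolic lungs against livers, and ATP6V0A2 1.63 and ACSL4 0.694 in metabolic subcutaneous tumours. The same held for ATP6V1B2 -0.101 and ACSL4 -0.0866 in ES-2 mini livers, and NMNAT1 0.307, B3GNT4 0.284, PPP2R5C 1.03, PTPRJ 0.157 and ACSL4 0.546 in ES-2 mini lungs. It also turned B3GNT4 0.678, KCNH3 0.0578, SLC10A7 0.422, NMNAT1 0.709 and ACSL4 0.633 in ES-2 mini lungs against livers. By rank aggregation of guides no gene passed (0) in phosphatase lungs, phosphatase lungs against livers, metabolic livers, metabolic lungs, metabolic lungs against livers and metabolic subcutaneous tumours. It passed 1 in phosphatase subcutaneous tumours, 2 in ES-2 mini livers, 1 in ES-2 mini lungs, 1 in ES-2 mini lungs against livers and 1 in SKHEP-1 subcutaneous tumours. With the median over guides 7 genes passed in phosphatase lungs, 2 in phosphatase lungs against livers, 15 in metabolic livers, 52 in metabolic lungs, 80 in metabolic lungs against livers and 1 in SKHEP-1 cultures. The median turned the sign of ECH1 -0.0822 and AGPS -0.129 in metabolic livers, and COQ10B 0.149, UGT2B10 -0.0124 and GNPAT 0.691 in metabolic lungs. It did so for INPP5E 0.125, AGPS 0.0853, ACSL4 0.0207, ECH1 0.306 and ECI1 -0.0429 in metabolic lungs against livers, and PPA1 -0.0682 in ES-2 mini lungs. The same held for AGPAT9 0.0559 in SKHEP-1 lungs. Without the guide filter 0 genes passed in metabolic livers, 50 in metabolic lungs, 54 in metabolic lungs against livers and 630 in metabolic subcutaneous tumours. Dropping the filter turned the sign of FAR1 -0.132 in metabolic livers, and NDST2 0.00679 and GNPAT 0.104 in metabolic lungs. It did so for ECH1 0.0987 in metabolic lungs against livers, and ACSF2 0.00502, GNPAT 0.463 and FAR1 0.458 in metabolic subcutaneous tumours. With guides at 100 or more in pre-injected cells 0 genes passed in metabolic livers, 347 in metabolic lungs against livers and 766 in metabolic subcutaneous tumours. The higher minimum turned the sign of ECI1 -0.0399 in metabolic lungs against livers.

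With the replicate number as a block 0 genes passed in metabolic livers, 1 in metabolic lungs, 119 in metabolic lungs against livers and 8 in ES-2 mini lungs. The block turned the sign of FAR1 -0.0110 in metabolic livers, and GNPAT 0.0387 in metabolic lungs. It did so for FAR1 0.201 in metabolic subcutaneous tumours. Without number 1, 2, 3 and 4 the blocked count of ES-2 mini lungs was 2, 6, 7 and 4. ACSL4 turned in sign with the block at -0.0613 without number 2 (livers), 0.309 without number 3 and 0.311 without number 4 (lungs) and 0.0835 without number 3 and 0.211 without number 4 (lungs against livers). Without the block the metabolic counts were 1 in livers, 155 in lungs and 222 in lungs against livers. In the phosphatase screen the block kept 8 of the 12 lung calls and 5 of the 7 calls of lungs against livers, and it changed no other count over 1.5 times. Outside the ES-2 mini screen same-number correlations held values below 0.1 in each combination of groups, so the numbers were not taken to pair the samples. They ran from -0.178 to 0.141 in the phosphatase screen and from -0.201 to 0.139 in the metabolic screen. In SKHEP-1 they ran from -0.112 to 0.439. SKHEP-1 cultures came closest to pairing, at 0.046 to 0.439 with pre-injected cells of the same number and at most 0.119 with others.

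Leaving out 1 library moved the counts over these ranges. The phosphatase counts ran for livers from 0 (without liver replicate 1) to 1 (without subcutaneous replicate 3), lungs from 0 (without subcutaneous replicate 1) to 37 (without lung replicate 3) and lungs against livers from 1 (without liver replicate 3) to 30 (without lung replicate 3). The metabolic counts ran for livers from 0 (without liver replicate 2) to 13 (without subcutaneous replicate 3), lungs from 25 (without subcutaneous replicate 2) to 248 (without lung replicate 5) and lungs against livers from 61 (without liver replicate 2) to 375 (without lung replicate 5). The SKHEP-1 counts ran for subcutaneous tumours from 0 (without subcutaneous replicate 2) to 3 (without subcutaneous replicate 1) and cultures from 0 (without pre-injected replicate 4) to 15 (without culture replicate 3).

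Genes whose sign turned when 1 library was left out had these ranges. The ES-2 mini fits here are without the block, so leaving out 1 library of a replicate number also shifts all genes by the offset between numbers. A turned sign in that screen can come from that offset alone. In metabolic livers ACSL4 ran from -1.26 (without subcutaneous replicate 3) to 0.0914 (without subcutaneous replicate 2), and ECH1 from -0.0602 (without subcutaneous replicate 2) to 0.616 (without subcutaneous replicate 3). In metabolic livers AGPS ran from -0.175 (without subcutaneous replicate 3) to 0.420 (without subcutaneous replicate 2), and ECI1 from -0.315 (without subcutaneous replicate 3) to 0.136 (without subcutaneous replicate 2). In metabolic lungs ECH1 ran from -0.0842 (without subcutaneous replicate 2) to 0.592 (without subcutaneous replicate 3), and AGPS from -0.547 (without subcutaneous replicate 3) to 0.0472 (without subcutaneous replicate 2). In metabolic lungs GNPAT ran from -0.404 (without lung replicate 5) to 0.0270 (without lung replicate 1), and ECI1 from -0.308 (without subcutaneous replicate 3) to 0.144 (without subcutaneous replicate 2). In metabolic lungs against livers ECH1 ran from -0.126 (without liver replicate 3) to 0.0790 (without liver replicate 1), and ECI1 from -0.105 (without lung replicate 5) to 0.0852 (without liver replicate 1). In ES-2 mini livers ACSL4 ran from -0.335 (without subcutaneous replicate 2) to 0.630 (without subcutaneous replicate 3). In ES-2 mini lungs PPP2R5C ran from -1.03 (without lung replicate 1) to 0.0575 (without lung replicate 2), and PTPRJ from -0.980 (without lung replicate 3) to 0.0878 (without lung replicate 2). In ES-2 mini lungs ACSL4 ran from -0.568 (without subcutaneous replicate 2) to 0.397 (without subcutaneous replicate 3), and PPA1 from -0.00688 (without lung replicate 1) to 1.20 (without lung replicate 2). In ES-2 mini lungs against livers B3GNT4 ran from -0.905 (without liver replicate 2) to 0.0264 (without lung replicate 2), and KCNH3 from -1.01 (without lung replicate 3) to 0.426 (without liver replicate 3). In ES-2 mini lungs against livers SLC10A7 ran from -1.18 (without lung replicate 3) to 0.481 (without liver replicate 3), and NMNAT1 from -0.925 (without lung replicate 3) to 0.266 (without liver replicate 3). In ES-2 mini lungs against livers ACSL4 ran from -0.507 (without liver replicate 2) to 0.223 (without lung replicate 4). In SKHEP-1 lungs ENTPD2 ran from -0.592 (without subcutaneous replicate 1) to 0.126 (without subcutaneous replicate 2).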

Other observations

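The tests of a shared transduced population and of the vacuolar ATPase in lungs against livers, and the share of used guides near the plasmid, were chosen only after the results were seen, and the others were written down before. Guides that were rare in the pre-injected cells of the metabolic screen kept the order of the plasmid library. Over 19745 guides below 30 in the cells, the rank correlation with the plasmid was 0.8295 to 0.904 in animals and 0.758 in the cells. Their median ratio to the plasmid was 0.749 to 1.01 in animals and 0.332 in the cells. The likeness was not limited to rare guides, since 59.5% to 77.0% of the 13354 guides used lay within 2-fold of the plasmid in animals and 21.4% in the cells. Why animal libraries lay nearer to the plasmid than the injected cells was not tested.

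Some knockouts that stood low outside lungs were relatively high in lungs, such as PPP2R1A in the ES-2 mini screen (6.39 in subcutaneous tumours, 8.93 in lungs), which a floor effect could give whatever the guide targets. The pattern was not general: in the phosphatase screen PPA1 (10.90 to 9.64) and SET (10.77 to 9.87) stood low and fell further in lungs, and CH25H, called higher in ES-2 mini lungs, did not stand low (10.91 in subcutaneous tumours). In the ES-2 mini screen, low control guides changed by -0.335 ± 0.292 (SE) against the other control guides, whereas the 7 genes called higher with the block, picked for being higher, stood 1.31 ± 0.201 over control guides. A rise of that size was not seen in low control guides, whose change ran from -0.818 (number 3) to 0.499 (number 2). These guides averaged 8.98 in livers, beside 9.55 for the 7 genes. PPP2R1A stood below them in livers in each replicate number (6.34 beside 7.95 in number 2), so a floor effect stays open for it. The 1 gene called lower has no part in these values. For the vacuolar ATPase in metabolic lungs, the list median of 0.16 lay at percentile 95.9 of lists matched by starting score (median of -0.03), which leaves it open for that comparison. In lungs against livers the list median of 0.23 lay at percentile 99.85 of matched lists (median of -0.05). A low pre-injected score alone does not account for it there. Its camera call there was lost with an estimated correlation, as given above, and matched lists of separate genes ignore such a correlation. The lists were not matched on the plasmid value, so nearness to the plasmid stays untested. In subcutaneous tumours against pre-injected cells the list median of 0.10 lay at percentile 99.9 of matched lists (median of -0.72). It thus stood above lists of like pre-injected score. Those lists were matched on the same single library from which the change is measured, so the explanation is not settled there.

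Liver replicate 4 of the ES-2 mini screen resembled liver replicate 2 (r = 0.885) more than its own subcutaneous tumour (r = 0.744). It correlated about as well with subcutaneous replicate 2 (0.740), and at 0.562 with lung replicate 2 beside 0.515 with lung replicate 4. Mixing of reads of liver replicate 2 into liver replicate 4 was not seen, and the reverse was not tested. The 25 guides highest in liver replicate 2 relative to subcutaneous replicate 2 changed by -0.330 in liver replicate 4. They changed by 0.487 in liver replicate 1 and by 0.574 in liver replicate 3. The value for liver replicate 4 is 1 mean against subcutaneous replicate 4, without a spread, so a mix is not excluded. A shared transduced population stays undecided, since the subcutaneous tumours of replicates 2 and 4 correlated at 0.547 beside 0.505 to 0.540 for other combinations.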
